A study of Mus musculus with 3 samples.

How the data were processed

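CAGE, which reads the capped 5′ ends of RNA, and PAS-Seq, which reads polyadenylated 3′ ends, were run on total RNA from wild-type C57BL/6J mouse testes. The series held 3 libraries, 1 per group: CAGE at 10.5 days post partum, CAGE in adults and PAS-Seq in adults. Per the labels, the PAS-Seq library was sequenced to a read length of 100 nt.

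The deposited data analysed here were 1 table for the whole series, a headerless BED table of 12 columns with 1 assembled transcript model per line. Its measurements were positions in base pairs, exon numbers and exon lengths. No value per library, read count or expression level was analysed here, so the depth of each library is unknown and the 3 libraries could not be compared with each other. Per the submitters' processing notes, TopHat2 2.0.4 and the mm9 build were used. How the CAGE and PAS-Seq reads set transcript starts and ends, how the models were assembled and how they were filtered are not given in the sources used here. Because no groups could be compared and no group had replicates, every test below runs over transcript models, loci or genes, which are features of 1 table and not replicates. Exact intervals cover counting error only.

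Models were sorted by the names and codes in the table, whose meaning is not given in the sources used here. RefSeq-derived models carried a gene symbol and a RefSeq accession. CUFF models carried an identifier of the form that the Cufflinks assembler gives, either with a gene symbol or alone. Another kind, called piRNA-named here, was named either as pi- followed by a gene symbol (gene-named) or as a chromosome, a cytogenetic band and a serial number (band-named). Each model also had a code that began with NM, NR, XX, PG or PI. All the gene-named loci carried PG models and the band-named loci PI models, except that 1 PI model was named for Hist1h1a. Numbers of models follow the codes (249 gene-named and 218 band-named models) and numbers of loci follow the names. RefSeq models of genes specific to other tissues were in the table, so the presence of a model is not a measure of expression. Of 23135 gene symbols, 99.1% matched a current or older symbol of the GRCm38.p6 gene tables, which were used for names only. Coordinates are those of the table, in mm9, counted from 1.

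Models whose exons overlapped by at least 1 bp on the same strand formed a locus. A head-to-head pair was 2 loci on opposite strands with the minus-strand start upstream of the plus-strand start by 1 to 500 bp, taking any start in each locus, and tail-to-tail pairs were defined likewise from ends. For shares of piRNA-named loci and RefSeq genes with a partner, only the starts of the piRNA-named or RefSeq-derived models themselves were set against any start on the other strand. Pair counts were compared with 1000 permutations of strands among the loci of each chromosome, a locus given the other strand being mirrored about its centre. The smallest p these permutations can give is 0.001. Loci with overlapping exons always lie on opposite strands, because same-strand overlaps were merged, and permuted strands do not keep this. For pairs of such loci the permutation mean can be too low. Starts or ends within 50 nt of each other were counted as 1. Distinct starts minus distinct ends per locus were tested by a sign-flip permutation with 100000 draws, and differences of medians of log2 length and of means between locus groups by permutation with 100000 draws. The smallest p from 100000 draws is 1e-05. Shares have exact Clopper-Pearson 95% intervals, except that the limit for 0 piRNA-named loci on X is 3 counts of the total, and were compared by Fisher's exact test. Tests were two-sided, except that the hypergeometric probability of 0 piRNA-named loci on X is one-tailed, with a threshold of 0.05, and families of tests were adjusted by Benjamini-Hochberg.

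The tests, 10 gene lists with 129 distinct symbols, and the rule for naming genes were fixed before the data were examined. A few list members are not reported here by name, though the counts include them. The rule takes all members of the lists that were found, the 5 loci with the most models, the 10 models with the longest spliced length, the 10 with the longest last exon, and the 10 head-to-head pairs with the largest summed spliced length, without unplaced sequences. Other genes named in the text were chosen after their values were seen, as were all comparisons of piRNA-named loci, of codes, of gene families and of CUFF-alone loci on X. The reading of a pair as any start of a locus was set after the table had been read and some close piRNA-named pairs had been noticed, but before pairs were counted. The version with outermost starts was computed as an alternative.

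The planned tests of sequence at starts, ends and splice sites were not run, because no mm9 genome was used here, and neither was the alternative that needed gene-model coverage. Nothing was filtered out for the main results: 69 models on unplaced or mitochondrial sequence and 17 models that repeat an earlier one stayed in. Alternatives covered pair distances of 200, 1000 and 5000 bp, multi-exon models, loci by genomic span, models without CUFF-alone entries and tolerances of 1, 20 and 200 nt for ends. The pair counter was tested on simulated strands over the 33191 placed loci. It called 1 of 20 random sets, and 400 planted pairs raised the count by 278 and were called. The sign-flip test called 5 of 100 sets with no shift. These random and unshifted sets were drawn as the tests draw their own permutations, so they check the code only. They do not show that permuted strands suit real loci. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.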

Results

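Transcript ends in mouse testis were mapped with CAGE for capped 5′ ends and PAS-Seq for polyadenylated 3′ ends. The series concerned a transcription factor of early meiosis, known from the study as A-MYB (Mybl1), and the loci that make PIWI-interacting RNAs (piRNAs), small RNAs that guide PIWI proteins in germ cells. It held 1 CAGE library at 10.5 days post partum, 1 adult CAGE library and 1 adult PAS-Seq library, all from wild-type C57BL/6J testes. The analysed table gave 50081 transcript models for the series as a whole. Many were RefSeq-derived, and how far the 3 libraries shaped the models is not given. No value per library was analysed. The depth of each library is therefore unknown, and the first wave of spermatogenesis at 10.5 days could not be set against the adult.

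The models formed 33254 loci and fell into 5 kinds. RefSeq-derived models made up 28031, CUFF models with a gene symbol 9495, and CUFF models alone 12088. A further 249 models were named for a piRNA locus within a gene and 218 for a piRNA locus by cytogenetic band. The piRNA-named models were the longest kinds: the median spliced length was 8520.5 nt for band-named models (quartiles 3772.25 and 25268.2) and 5275 nt for gene-named models (3083 and 7648). RefSeq-derived models had a median of 2371 nt (1318 and 3756) and CUFF-alone models 1476 nt (884 and 2323). Single-exon models were 71.5% of CUFF-alone models (95% interval 70.7 to 72.3), 41.7% of band-named models (35.1 to 48.6), 10.9% of RefSeq-derived models (10.5 to 11.3) and 2.41% of gene-named models (0.889 to 5.17). Of the loci, 23255 held 1 model and 9999 held at least 2. CUFF-alone models formed 10519 loci, of which 8242 (78.4%, 77.6 to 79.1) had single-exon models only. These differences between kinds of model were described and not tested.

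**Figure D1:**
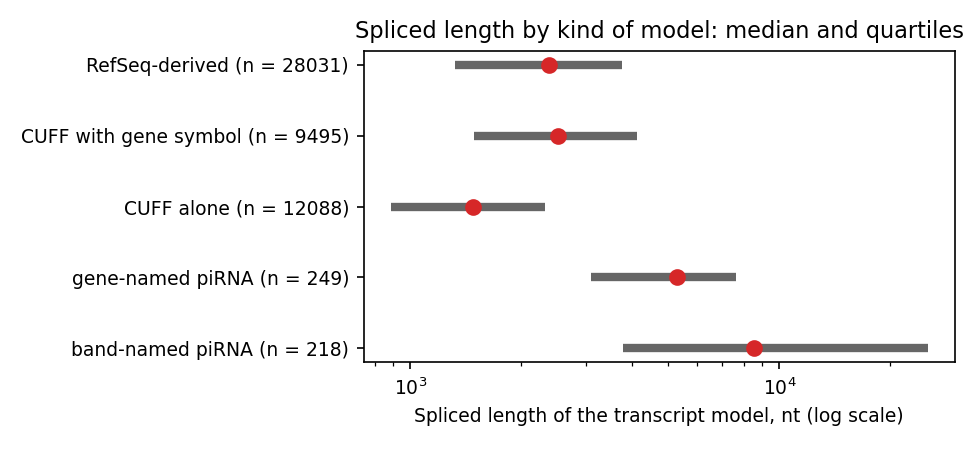
Spliced length in nt on a log axis for the 5 kinds of transcript model, with the median as a point and the quartiles as a bar. Band-named and gene-named piRNA models have medians of 8520.5 and 5275 nt, above the 2371 nt of RefSeq-derived models.

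The longest models joined muscle, imprinting and piRNA transcripts. The longest spliced model was the second model of the gene-named piRNA locus pi-D10Wsu102e on chromosome 10 (82822986 to 82950827, mm9), at 122736 nt with a last exon of 122379 nt. Its last exon ran 119247 nt beyond the RefSeq end of D10Wsu102e, far more than at any other gene-named locus. A CUFF model of 102299 nt at the locus of Ttn, the giant sarcomere protein titin, and 2 RefSeq models of Ttn of 101674 and 81931 nt followed, all coded XX. Kcnq1ot1, the long antisense RNA of an imprinted domain, had a single exon of 83437 nt. The remaining places were taken by the band-named loci 3-qA2-617 (69605 and 67058 nt, chromosome 3, 20301594 to 20405121) and 2-qE1-35981 (66885 and 57936 nt, chromosome 2, 92381299 to 92449301) and by CUFF.14919.1 (56690 nt), which lies over 2-qE1-35981. Among the longest last exons, the band-named loci 7-qD1-16444 (56596 nt), 4-qC5-17839 (51472 nt), 10-qB4-6488 (49817 nt) and 14-qA3-19970 (48098 nt) were single-exon transcripts. CUFF.18210.1 (55494 nt), which lies over 4-qC5-17839, and CUFF.26925.1 (47856 nt), which lies over 9-qA5.3-24188, completed that set. The locus with the most models, 37, was the protocadherin alpha and gamma cluster on chromosome 18 (37089939 to 38001526). The locus of pi-Ip6k1 followed with 17, of which 14 were piRNA-named, and Pcdh15, Plec and Hmga1 with 16 each.

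Genes of the piRNA pathway, meiosis and spermatids were almost all in the table under a code other than XX, and genes of other tissues mostly were not. In the piRNA pathway, 20 of 21 genes had such a code: Piwil1, Piwil2, Ddx4, Mael, Mov10l1, Tdrd1, Tdrkh, Tdrd5, Tdrd6, Tdrd7, Tdrd9, Tdrd12, Rnf17, Pld6, Asz1, Gtsf1, Fkbp6, Henmt1, Pnldc1 and Exd1. The exception was Piwil4, the PIWI protein of fetal prospermatogonia, whose 1 model was coded XX. All 22 genes of meiotic prophase had it. Among these were the synaptonemal complex genes Sycp1, Sycp2, Sycp3, Syce1, Syce2, Syce3 and Tex12, the axis and cohesin genes Hormad1, Hormad2, Rec8 and Smc1b, the recombination genes Spo11, Dmc1, Mlh3, Msh4, Msh5, Prdm9, Meiob and Spata22, and Stra8 and Ccna1. All 17 spermatid genes had it, among them the protamines Prm1 and Prm2, the transition proteins Tnp1 and Tnp2, and the flagellar genes Akap4, Odf1, Odf2 and Catsper1, with Acrv1, Pgk2, Ldhc, Hspa1l, Acr, Zpbp, Spaca1, Gapdhs and Smcp.

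Most members of the lists for other testis cell types also had such a code. Of 11 germline transcription factors, 10 had a code other than XX (Mybl1, Mybl2, Rfx2, Sohlh1, Sohlh2, Taf7l, Crem, Tcfl5, Zbtb16 and Dmrt1) and Nobox, an oocyte factor, had not. Of 11 spermatogonial genes, 10 had it (Zbtb16, Kit, Dmrt1, Uchl1, Gfra1, Nanos3, Lin28a, Sall4, Id4 and Dazl) and Nanos2 had not. All 11 Sertoli genes found had it (Sox9, Wt1, Gata4, Amh, Amhr2, Fshr, Inha, Clu, Dhh, Cldn11 and Gata1), whereas Rhox5 was not found under that or an older symbol. So did all 8 Leydig genes (Star, Cyp11a1, Cyp17a1, Hsd3b6, Hsd3b1, Insl3, Lhcgr and Hsd17b3) and 8 of 9 peritubular, vascular and immune genes (Acta2, Myh11, Pecam1, Cdh5, Ptprc, Cd68, Emr1 and Csf1r, but not Vwf). Of the 10 genes of other tissues, 2 had it, Ins2 among them. Alb, Myh6, Gfap, Krt14, Fabp1, Umod, Cyp7a1 and Pou1f1 had XX models alone. Among 10 housekeeping genes, Actb, Ppia, Tbp, Hprt, Eef1a1, Rplp0, Tubb5, Hsp90ab1 and Polr2a had it and Gapdh had not. The planned test of mere presence did not separate any list from the other-tissue list (Fisher's exact test, p = 1 for each of 9 lists), since 10 of 10 other-tissue genes were present. The test of codes, chosen after the table was seen, separated all 9 lists from it, with Benjamini-Hochberg adjusted p from 3.85e-05 for meiotic prophase to 0.00548 for housekeeping genes. The other-tissue list of 10 genes lay below the background, in which 13970 of 22366 RefSeq genes (62.5%, 61.8 to 63.1) had a code other than XX. This background includes microRNA, olfactory and vomeronasal receptor genes, nearly all with XX models alone. Without them the share was 61.8% on X and 68.6% on autosomes, and the lists were not tested against that background. Against all other RefSeq genes, 5 lists were higher: meiotic prophase (adjusted p = 0.000592, Fisher's exact test over 10 lists), spermatids (0.0027), piRNA pathway (0.00351), Sertoli cells (0.0184) and Leydig cells (0.0480). The other-tissue list was lower (Fisher's exact test, adjusted p = 0.0184). Germline transcription factors and spermatogonia (Fisher's exact test, adjusted p = 0.0779 for both), housekeeping genes (0.113) and peritubular, vascular and immune genes (0.167) did not pass. The meaning of XX is not given, so this does not measure expression.

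**Figure D2:**
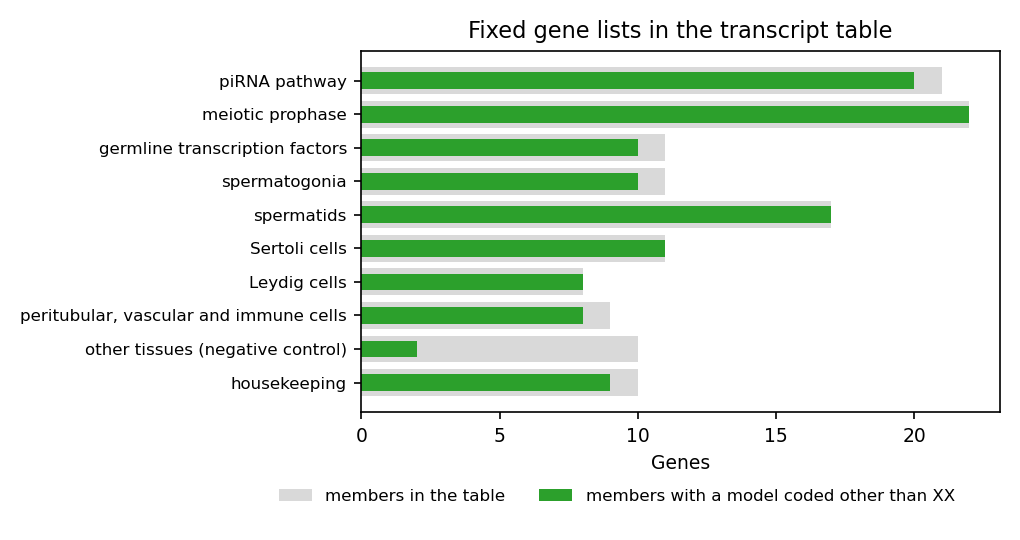
Number of genes of each fixed list in the table (grey bars) and number with at least 1 model coded other than XX (green bars). The other-tissue list has 2 of 10 such genes, and the meiotic prophase list has 22 of 22.

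Several of these genes had more than 1 start or end. Mybl1 (chromosome 1, 9657610 to 9690681, minus strand) had 3 models with 3 starts and 2 ends, the longest with 15 exons and 5077 nt. Sycp2 had 5 models with 5 starts and 4 ends, Tdrd7 had 4 starts and 2 ends, and Exd1 had 2 starts and 3 ends. Crem, a transcription factor of spermatids, had 11 models with 3 starts and 2 ends, all 11 of them RefSeq-derived. Stra8, Sycp3, Prm1, Prm2, Tnp1 and Tnp2 had 1 model each.

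Opposite-strand loci lay head to head more often than permuted strands gave. There were 1721 head-to-head pairs with starts within 500 bp, against a permutation mean of 876 (SD 23.9, range 808 to 955), 1.96-fold (p = 0.001, the smallest the permutations can give). They took in 3420 loci, 10.3% of all. Both loci had a gene symbol in 990 pairs (57.5%), and a CUFF-alone locus faced one with a symbol in 554. Of 22 meiotic genes, 6 had a partner. Among them, Tex12 faced Il18, Smc1b faced Ribc2, Msh5 faced Clic1, Spata22 faced Aspa and Ccna1 faced 4931419H13Rik. In the piRNA pathway, Mov10l1 faced the piRNA-named locus pi-Mlc1, Exd1 faced 1500003O03Rik and Gtsf1 faced a CUFF-alone model. Among spermatid genes, Tnp1 faced 1700027A15Rik, Acrv1 faced 1700027I24Rik and Zpbp a CUFF-alone model. Wt1 faced AI314831, and Rfx2 a CUFF-alone model. No gene of the spermatogonial, Leydig, peritubular, vascular and immune, other-tissue or housekeeping lists had a partner, and no list was tested against other genes for this. Tail-to-tail pairs of ends, in contrast, numbered 610 against a permutation mean of 827 (SD 24.98, range 758 to 908), 0.738-fold (p = 0.001, again the smallest possible). The direction turned in part of the alternatives: with multi-exon models only the ratio was 1.26, and without CUFF-alone models it was 1.20 (permutation p = 0.001 for both). The RefSeq models in the table mean that these counts partly describe the annotation.

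**Figure D3:**
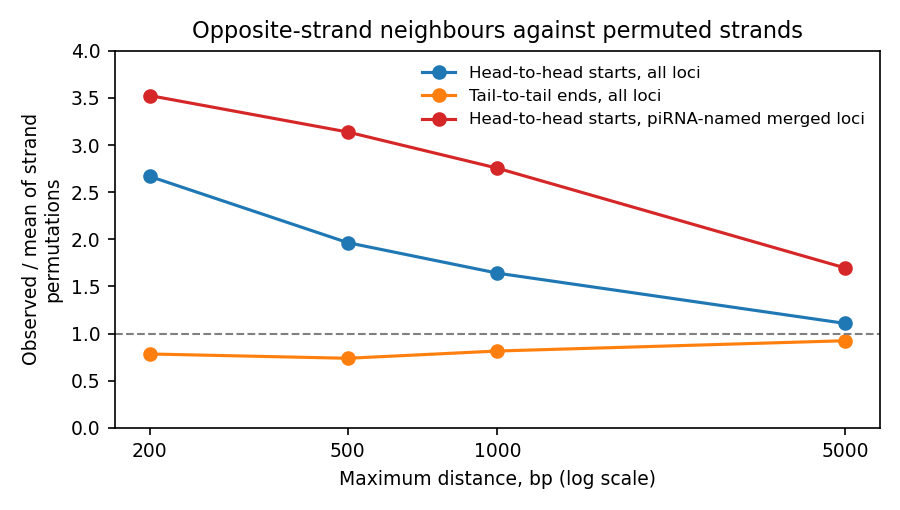
Observed number divided by the mean of 1000 strand permutations (1 marks equality, dashed) against the maximum distance between starts or ends in bp on a log axis. Head-to-head starts of all loci fall from 2.67 at 200 bp to 1.11 at 5000 bp and piRNA-named merged loci from 3.52 to 1.70, whereas tail-to-tail ends of all models stay below 1, unlike the 1.26 found with multi-exon models at 500 bp.

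The piRNA-named loci were of 2 forms that differed in length and splicing. The comparisons of these loci were chosen after the table was seen and form a family of 8 tests. The longest model of the 100 band-named loci had a median of 14699 nt (quartiles 6727.75 and 32187.2), against 7440 nt (5633.75 and 9278.25) for the 114 gene-named loci. The difference was 0.98 on the log2 scale, 1.98-fold (permutation p = 1e-05, the smallest possible, adjusted 1.6e-05). Among 13822 RefSeq genes coded NM or NR the median was 2618 nt. All models were single-exon in 47 of 100 band-named loci (47%, 36.9 to 57.2) and in 2 of 114 gene-named loci (1.75%, 0.213 to 6.19; Fisher's exact p = 1.62e-16, adjusted 1.30e-15). With multi-exon models only, the length difference fell to 0.38 on the log2 scale (permutation p = 0.00322). Gene-named loci carry a gene symbol, and 112 had a RefSeq model of that symbol. The difference in splicing therefore cannot be separated from the naming.

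Band-named piRNA loci often shared a start region with a transcript on the other strand. A head-to-head partner within 500 bp was found for 40 of 100 band-named loci (40%, 30.3 to 50.3), 21 of 114 gene-named loci (18.4%, 11.8 to 26.8) and 2131 of 13822 RefSeq genes (15.4%, 14.8 to 16.0). Band-named loci exceeded gene-named loci (odds ratio 2.95, Fisher's exact p = 0.000766, adjusted 0.000875) and RefSeq genes (odds ratio 3.66, p = 3.19e-09, adjusted 1.28e-08). All piRNA-named loci together exceeded RefSeq genes (odds ratio 2.19, Fisher's exact p = 1.45e-06, adjusted 3.87e-06). Gene-named loci alone gave an odds ratio of 1.24 against RefSeq genes, which did not pass the test (Fisher's exact p = 0.363). Against all RefSeq genes, those coded XX included, the odds ratios were 1.92 for gene-named loci (Fisher's exact p = 0.0132), 3.39 for all piRNA-named loci and 5.67 for band-named loci. The partner was itself piRNA-named for 30 of the 61 partnered loci, 29 of the 40 band-named and 1 of the 21 gene-named. Both members of such a pair count as separate loci in the tests above, so their p-values overstate the evidence. When piRNA-named models were not counted as partners, other models at the same partner loci still counted. Band-named and gene-named loci then no longer differed past the threshold (odds ratio 1.57, Fisher's exact p = 0.239). Band-named loci gave an odds ratio of 1.83 against RefSeq genes (Fisher's exact p = 0.0119). Members of piRNA-named pairs could still count through such models, so this does not show an excess apart from those pairs.

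The 30 loci with a piRNA-named partner formed 15 pairs in which both strands carried a piRNA-named transcript, with the nearest non-overlapping starts of their piRNA-named models 39 to 181 bp apart (median 126). With the starts of all models in the merged loci, the nearest were 6 to 169 bp apart. The rule of largest summed length named 10 pairs, and in 9 of them both loci were piRNA-named. The rule takes all models of the merged loci, while the positions, lengths and distances of these 9 are given for piRNA-named models alone. On chromosome 7, 7-qD1-9417 (77019096 to 77054469, longest model 35374 nt) faced 7-qD1-16444 (77054650 to 77111245, 56596 nt) across 181 bp. On chromosome 17, 17-qA3.3-27363 (27425221 to 27461973, 36753 nt) faced 17-qA3.3-26735 (27462142 to 27504428, 41944 nt) across 169 bp. On chromosome 12, 12-qE-23911 (40241 nt) and 12-qE-7089 (35818 nt) started 100 bp apart. On chromosome 9, 9-qA5.3-24188 (42650 nt) and 9-qA5.3-1495 (27693 nt) started 123 bp apart, and 9-qC-31469 (42535 nt) and 9-qC-10667 (26985 nt) 159 bp apart. The others were 15-qD1-17920 with 15-qD1-4001 (145 bp), 6-qF3-8009 with 6-qF3-28913 (59 bp), 5-qF-14508 with 5-qF-14224 (43 bp) and 7-qD2-24830 with 7-qD2-11976 (126 bp). With all models the distance was 79 bp for 7-qD1, 76 bp for 12-qE, 122 bp for 9-qC, 36 bp for 15-qD1 and 6 bp for 6-qF3, and the same as above for the other 4. The tenth joined 2-qE1-35981 to a CUFF-alone locus whose nearest start was 164 bp away. Some piRNA-named loci faced a gene, and these examples, measured from the starts of piRNA-named models, were chosen after their values were seen. The start of pi-Mlc1 lay 241 bp from that of Mov10l1, which encodes a helicase needed to make piRNAs. The start of pi-Hmbox1 lay 183 bp from Ints9, pi-Gtf3c4 65 bp from Ddx31 and pi-Ipmk 64 bp from Cisd1.

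**Figure D4:**
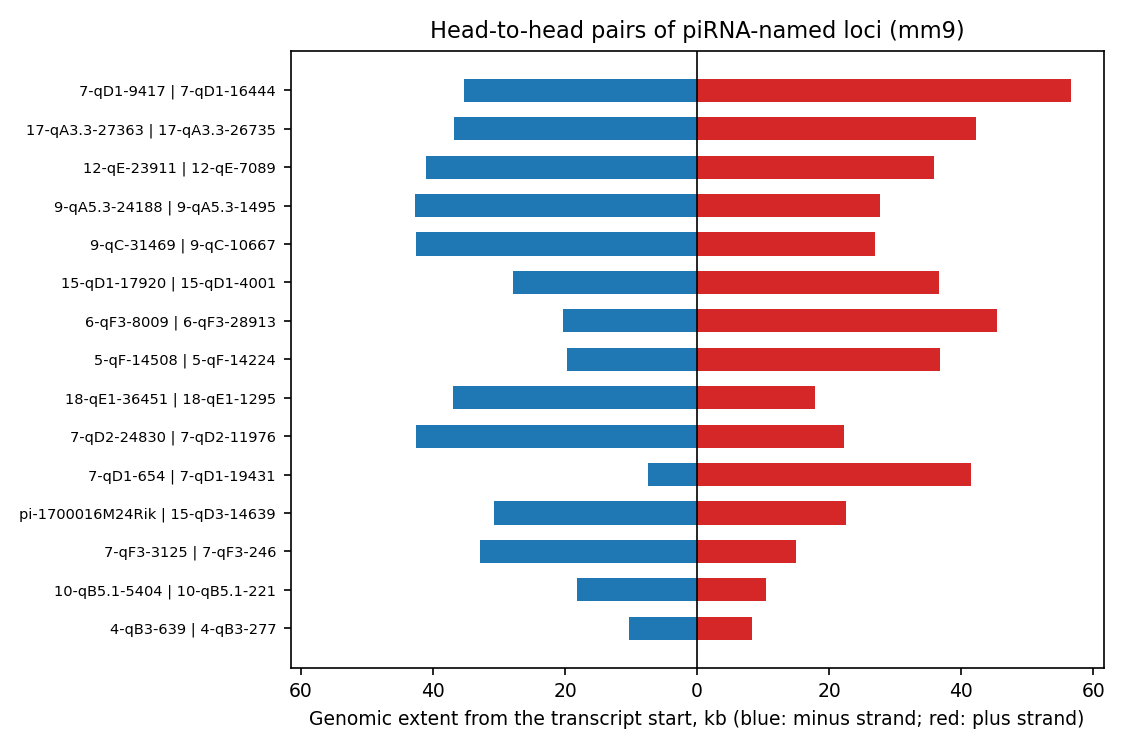
The 15 head-to-head pairs of piRNA-named loci, 1 per line, with the genomic extent in kb of the minus-strand locus to the left (blue) and the plus-strand locus to the right (red), each drawn from its outermost start. The longest of them, 7-qD1-16444, spans 56596 bp, and the nearest non-overlapping starts of each pair lie 39 to 181 bp apart when piRNA-named models alone are taken, as drawn here, a gap too small to see at this scale.

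Alternative starts outnumbered alternative ends over all loci, and the reverse held at piRNA-named loci. Over 9999 loci with at least 2 models there were 1.89 distinct starts (SD 0.891) and 1.73 distinct ends (SD 0.740) per locus. The mean difference was 0.161 (SD 0.990), with more starts at 3231 loci, more ends at 2137 and equal numbers at 4631 (sign-flip permutation p = 1e-05, the smallest possible). The piRNA-named models of 153 loci gave a difference of -0.752 (SD 0.891), with more ends at 104 loci and more starts at 16 (sign-flip permutation p = 1e-05). Against 9786 loci without a piRNA-named model, whose mean was 0.177 (SD 0.977), it differed by -0.928 (permutation p = 1e-05, adjusted 1.6e-05). The first side of that comparison counts piRNA-named models alone and the second counts all models. With all models counted on both sides, the 213 merged loci with a piRNA-named model had a mean of -0.568 and differed by -0.745 (permutation p = 1e-05). Band-named loci had 1.10 starts (SD 0.302) and 2.14 ends (SD 0.767) over 70 loci, and gene-named loci 1.46 starts (SD 0.591) and 1.96 ends (SD 0.652) over 83 loci. Band-named loci differed from gene-named loci by -0.537 (permutation p = 0.00016, adjusted 0.000213). RefSeq-derived models alone gave a difference of 0.259 over 3776 loci, so the excess of starts was also a property of the annotation. How starts and ends of piRNA-named models were set is not given, and the 213 merged loci still include these models. The excess of ends there cannot be told apart from how that set of models was built.

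At some gene-named piRNA loci the furthest end lay past the RefSeq end of the gene. Of 112 loci with a RefSeq model of the same symbol, 36 had their furthest end more than 50 nt downstream of the RefSeq end, 4 upstream and 72 within 50 nt (exact sign test p = 1.86e-07, chosen after the table was seen). The median shift was 0. Each side took the furthest end over all its models, so unequal numbers of models can tilt these counts. The sign test does not allow for this. With only the first-numbered model of each locus in place of the furthest end, the excess of downstream over upstream ends fell from 32 to 16 loci (exact sign test p = 0.0293). The RefSeq side still took the furthest of its models there. At pi-Igsf9b the end lay 22966 nt downstream, at pi-Zbtb37 14834 nt, at pi-Kcng3, named for a potassium channel subunit, 11933 nt, and at pi-Hmbox1 10616 nt. Extensions at pi-Acvr2b, an activin receptor gene (8408 nt), pi-Cbl, a ubiquitin ligase gene (6283 nt), pi-Eif2c2, the Argonaute 2 gene (5776 nt), and pi-Foxo3 (3940 nt) were among the others. Outermost starts, taken likewise, lay more than 50 nt upstream at 32 loci, downstream at 9 and within 50 nt at 71 (exact sign test p = 0.000431). With a tolerance of 20 nt the excess was not past the threshold (exact sign test p = 0.268). With only the first-numbered model of each locus, the excess of downstream over upstream starts was 2 loci (exact sign test p = 0.878), turning the direction.

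The autosomes carried all 467 piRNA-named models, and neither X nor Y carried any. With 0 of 214 piRNA-named loci on X, counting error allows a share of up to 1.40% (3 counts of the total), while X held 3.74% of placed loci. Chromosome 10 had the most merged loci with a piRNA-named model, 18, followed by chromosomes 1 and 11 with 17 each. Single-exon loci were 31.6% of 1240 loci on X (29.0 to 34.3), 34.9% of 31905 autosomal loci (34.4 to 35.4) and 69.6% of 46 loci on Y (54.2 to 82.3). X lay -3.30 points from the autosomes (odds ratio 0.862, Fisher's exact p = 0.0164), and -5.31 points without models under 200 nt (Fisher's exact p = 0.000127). CUFF-alone loci were 19.1% of loci on X and 32.1% on autosomes (a difference of -13.0 points, Fisher's exact p = 8.19e-24, chosen after the table was seen).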

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

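The alternatives for the planned results were fixed before the data were examined, except those with outermost positions, overlapping starts, without CUFF-alone models or with RefSeq-derived models only; these and all alternatives for piRNA-named loci were chosen after seeing the data. Of 34 planned values, 29 kept their direction and side of the threshold or their size, and of 69 added ones, 64 did. Not all of these could change: the share of single-exon models and the median length do not depend on building loci by genomic span. The head-to-head excess held at every distance and model set run, between 1.11-fold at 5000 bp and 2.67-fold at 200 bp, with 1.81-fold for outermost starts. For piRNA-named merged loci it lay between 1.70-fold at 5000 bp and 3.52-fold at 200 bp, with 2.61-fold for outermost starts, where 29 loci were in a pair against 64. Tail-to-tail pairs reversed, to 1.26-fold with multi-exon models only and 1.20-fold without CUFF-alone models; the cause was not tested. Leaving out single-exon models gave 21679 loci and a median length of 2494 nt, and leaving out models under 200 nt gave 24.3% single-exon models and a median of 2158 nt, both by construction. Not counting piRNA-named models as partners, with other models at the same loci still counted, ended the difference between band-named and gene-named loci (odds ratio 1.57). Partners were fewer there by construction. Taking all RefSeq genes as the comparison brought gene-named loci past the threshold (odds ratio 1.92), and the cause of that change was not tested. For starts of gene-named loci against RefSeq, a tolerance of 20 nt gave a downstream minus upstream number of -10, no longer past the threshold, and the first-numbered models gave 2, a reversal; the cause was not tested. The same models brought the excess of downstream ends from 32 to 16 loci. The excess of distinct starts held under all 6 alternatives, from 0.110 (within 200 nt) to 0.259. Leaving out models under 200 nt moved the X difference in single-exon loci from -3.30 to -5.31 points. Older symbols added no list member. The sequence tests, with their 3 alternatives, and the alternative of covered gene models were not run. Depth is unknown, so what it limits could not be judged. No paired analysis was possible because each group had 1 library and no value per library was analysed.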

Other observations

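All tests in this part were chosen after the results they bear on were seen, and the transcript models, loci and genes they run over are not replicates. Gene families differed widely in how often all of their models were coded XX. Every one of 586 microRNA genes had XX models alone, as did 1057 of 1117 olfactory receptor genes (94.6%, exact interval 93.1 to 95.9), 184 of 196 Vmn1r and 113 of 120 Vmn2r vomeronasal receptor genes, 50 of 52 keratin-associated protein genes, 25 of 27 prolactin family genes and 33 of 38 taste receptor genes. At the other end were 1 of 67 histone genes (1.49%, 0.0378 to 8.04), 1 of 51 genes with symbols starting Rps, most of them ribosomal proteins, 2 of 38 kinesin genes and 13 of 144 Ccdc genes (9.03%, 4.89 to 14.9). Among X-linked reproductive families, 26 of 30 Rhox homeobox genes (86.7%, 69.3 to 96.2) and 8 of 8 Ssxb genes had XX models alone. Of the 10 Cypt genes, which are expressed in spermatids, none had XX models alone (0%, 0 to 30.8). Of 44 beta-defensin genes, many of them epididymal, 33 had XX models alone (75%, 59.7 to 86.8).

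On X, 553 of 971 RefSeq genes (57.0%, 53.8 to 60.1) had a model coded other than XX, against 13407 of 21383 autosomal genes (62.7%, 62.0 to 63.3; odds ratio 0.787, Fisher's exact p = 0.000327). Without microRNA, olfactory and vomeronasal receptor genes the shares were 61.8% and 68.6% (odds ratio 0.741, Fisher's exact p = 2.74e-05).

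The first pattern is the head-to-head arrangement of piRNA-named loci. Local crowding of loci predicts a number of merged loci in a pair within that of permuted strands, but 64 of 213 were in a pair against a permutation mean of 20.4 (range 9 to 37), with p = 0.001, the smallest the permutations can give. The permutation mean can be too low here, since loci with overlapping exons cannot share a strand but permuted strands ignore this. Pairs counted from outermost starts do not overlap, and 29 loci were then in a pair, 2.61-fold the permutation mean (strand permutation p = 0.001). The excess held there with a smaller count. Partners that are assembly fragments without a gene name predict mostly CUFF-alone partners. Loci whose partners were all CUFF-alone made up 16.4% of partnered loci (10 of 61, exact interval 8.15 to 28.1). However, 30 of the 61 had a piRNA-named partner and could not count as CUFF-alone, so this share cannot decide that explanation. How the authors drew the borders of these loci is not given in the sources used here and stays open, as it could have split a single region with both strands into a pair. As a hypothesis, shared start regions may be more frequent at longer piRNA-named loci: 40 of 107 loci above the median length of 8315 nt had a partner against 21 of 107 at or below it (odds ratio 2.44, Fisher's exact p = 0.00616), with 29 of 50 against 11 of 50 among band-named loci (p = 0.000449) but 9 of 57 against 12 of 57 among gene-named loci (p = 0.63), and both members of a pair count here. No biological group was named by the design, so no biological explanation was tested.

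The second pattern is the lack of piRNA-named loci on X. Chance placement among all loci would put 7.96 merged loci on X and gives a one-tailed hypergeometric probability of 0.000293 for none. With loci within 1 Mb counted as 1, 154 clusters remain, 5.75 would fall on X and the hypergeometric probability of none is 0.0028. The clusters were set against the share of unclustered loci on X, and no other distance was tried. Clustering at that distance alone did not bring the probability above the threshold, but this does not exclude clustering. Among loci that hold a RefSeq-derived model, with or without others, 136 merged loci with a piRNA-named model were left, 5.77 would fall on X and the probability of none was 0.00271. The authors' rule for naming loci is not given and stays open, and no biological explanation was tested.

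The third pattern is the code XX. If XX marked genes not expressed in testis, genes of other tissues should carry it more often than germline genes. They did: 59 of 60 genes of the piRNA, meiotic and spermatid lists had another code, against 2 of 10 (Fisher's exact p = 4.17e-08). These are the list counts given above, seen before the prediction was written, so they are not separate support. RefSeq-derived models at piRNA-named loci go against a lack of expression in testis as the whole meaning of XX. Of these models, 166 of 187 were coded XX (88.8%, 83.3 to 92.9) against 34.9% elsewhere (Fisher's exact p = 1.44e-52). Overlap with a piRNA-named model is not the whole cause either, as it covers 1.68% of RefSeq-derived models coded XX (1.43 to 1.95), and Gapdh and nearly all CUFF-alone models (12086 of 12088) also carry XX. The code may therefore mark models left out of a final set for more than 1 reason, and no biological explanation was tested.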
